A study of Mus musculus with 16 samples.

How the data were processed

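The deposited tables held CUT&RUN measurements from adult mouse left ventricle. CUT&RUN is an assay in which an antibody guides a protein A and micrococcal nuclease fusion to chromatin, and the DNA released around the antibody's target is sequenced. Nuclei on concanavalin A beads were incubated with the antibody overnight and libraries were made with a ligation kit, per the labels' protocols. The 16 libraries covered 4 antibodies, 2 genotypes and 2 replicates of each. The antibodies were against H3K27ac, the acetylation of active promoters and enhancers, H3K4me1, the mark of enhancers, H3K27me3, the mark of Polycomb repression, and CTCF, the DNA-binding protein at insulators and loop anchors. The genotypes were the FVB control strain and mice lacking an enhancer of Pitx2 that the labels call Enh20k. The coordinates of the deleted interval are not given in the sources used here.

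Each antibody had 1 table with 1 line per region and 1 column per library. The deposited values are a normalized signal, the tags of a library in a region scaled by the authors to 10000000 tags of that library and rounded to 2 decimals, per the file headers of the H3K4me1, H3K27me3 and CTCF tables. The header of the H3K27ac table gave no library totals, and its values were taken to be in the same unit because they moved in the same kind of steps. The regions were one set for all 4 libraries of an antibody, annotated by HOMER on the mouse build mm10 with the nearest transcription start, per the file headers. Bowtie2 2.3.4.3, HOMER 4.10.3, R 3.6.1 and limma 3.40.6 were used, with builds mm10 and R64, per the submitters' processing notes, which give no role for any of them. How regions were called, whether duplicates were removed and any background subtraction are not given in the sources used here. A tag is the unit HOMER counts.

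The values of a library were multiples of a single step. The step was worth 1 tag in H3K27me3 and 0.5 tags, taken as 1 read end, in the other 3 antibodies. Every value came out whole in every library, a share of 100%, within a tolerance of 0.011 or 0.0002 of the value, whichever was larger. Library totals recovered from the steps differed from those in the headers by far less than 1%. In units of 1e6 tags, totals were 22.2 to 29.6 for H3K27ac, 26.0 to 33.9 for H3K4me1, 22.1 to 27.5 for H3K27me3 and 19.3 to 24.9 for CTCF. A value of 1 therefore stood for about 2 to 3 tags, so values under about 5 rest on few molecules. Any PCR duplicates that were not removed are part of the counts, which carry no molecular identifiers. Counting precision alone would then understate the error.

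The tests fixed before the data were examined were count tests, with limma on log2(value + 1) as the choice for a normalized unit. Because the tables hold a normalized signal and not counts, limma 3.58.1 in R 4.3.3 was used, with a trended variance prior, no block, the deposited scaling and a pseudocount of 1. A fold change is therefore on the log2(value + 1) scale and understates the change of low regions. An alternative listed beforehand, with no scaling factors, is the same fit by construction. Regions entered the test if they passed the filterByExpr function of edgeR 4.0.16 on the recovered reads with a minimum count of 10. This kept 127186 of 127186 regions for H3K27ac, 126153 of 126153 for H3K4me1, 97610 of 104376 for H3K27me3 and 31150 of 31153 for CTCF. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within an antibody, and the threshold was 0.05. Deletion libraries were compared with control libraries within each antibody, and log2 fold changes are deletion minus control. The replicates are not stated to be separate animals, so p-values measure only the spread between these libraries, which may be technical.

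Gene values are sums over the regions whose nearest transcription start is that gene's and lies within 10 kb. Gene symbols that a spreadsheet had turned into dates were restored through their Entrez identifiers in 199 H3K27ac, 168 H3K4me1, 88 H3K27me3 and 40 CTCF regions, with a table of gene names for assembly GRCm38.p6. Regions within 1.5 Mb of the Pitx2 start, at chromosome 3, 129199878 to 129219594 on mm10, were also adjusted over that window alone. The 24 gene lists, of 514 genes, were fixed before the data were examined. They were tested with camera on log2(value + 1) of the gene values, with a preset correlation of 0.01, where at least 3 genes were measured. The plan had named voom values, which were not used for the lists. The same test with an estimated correlation and the rotation test fry were run beside it. Genes of the lists under another symbol in the tables were matched only through a single direct synonym, which applied to Aopep and Ccdc109b. This matching was tightened after list results had first been seen, which raised the passing lists from 11 to 12 in H3K27ac and from 6 to 7 in H3K27me3. Chromosome 3 outside the window was compared with the other autosomes by Fisher's exact test, and fold changes of overlapping regions (1 bp or more) were correlated across regions.

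The named genes followed a rule fixed before the data were examined. It took Pitx2 and Enpep whatever their result, every region in the Pitx2 window past the threshold over all regions or over the window, and the 3 regions with the lowest p per direction. It also took up to 12 genes per direction past the threshold whose libraries did not overlap between genotypes, or the 6 with the lowest p where fewer than 6 passed, leaving out unnamed gene models, and up to 4 members of each passing list. Names outside this rule are marked as chosen after their values were seen.

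The alternatives listed before the data were examined were DESeq2 size factors, loess offsets, the Wald test of DESeq2 1.42.0, voom, no filter, the replicate number as a block, and leaving out each library in turn. They also held gene distances of 2 and 50 kb, the other set tests, an unadjusted threshold for chromosome 3, and a stricter overlap or abundance for the correlations. Those chosen after seeing the data were TMM factors, the edgeR quasi-likelihood test on recovered reads with and without TMM factors, pseudocounts of 0.5 and 5, a robust variance prior, a filter at a value of 10, and the gene lists without each library in turn.

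The fits were tested on simulated data drawn from the real region means and depths, with 1 common spread per antibody and 200 regions changed. The changed regions averaged at least 20 recovered reads, and no shift between whole libraries was simulated. Recovery in the real libraries may therefore be lower. At a 2-fold change, limma recovered 19% of them among 127186 H3K27ac regions, 69.5% among 126153 H3K4me1 regions, 49% among 97610 H3K27me3 regions and 39% among 31150 CTCF regions. At a 4-fold change it recovered 87.5%, 98%, 94% and 96.5% in that order. A list of 20 genes shifted 1.41-fold was found at an unadjusted p under 0.05 in 20 of 20 draws for each antibody. An unshifted list was called in 2 of 20 draws for H3K27ac, 1 for H3K4me1 and 0 for H3K27me3 and CTCF. The simulated genes were independent, so these draws do not test the preset correlation.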

Results

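Left ventricles of adult FVB control mice and of mice lacking the Pitx2 enhancer Enh20k were profiled for H3K27ac, H3K4me1, H3K27me3 and CTCF, with 2 libraries per genotype and antibody. Pitx2 encodes the homeobox transcription factor of left-right asymmetry whose locus carries the strongest common risk for atrial fibrillation. The series asks how distant enhancers of Pitx2 act on its promoter and on the predisposition to that arrhythmia. The tables measured 127186 regions for H3K27ac, 126153 for H3K4me1, 104376 for H3K27me3 and 31153 for CTCF. The share of a library's tags inside the regions was 29.5 to 35.5% for H3K27ac, 51.1 to 55.2% for H3K4me1, 30.3 to 32.4% for H3K27me3 and 3.15 to 6.51% for CTCF. The lowest CTCF share was that of control replicate 2. Libraries of 1 genotype differed by more than counting noise for every antibody, with a chi-square per degree of freedom from 1.13 in the H3K4me1 controls to 2.88 in the H3K27me3 deletion libraries, so each library was counted as 1 sample.

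At Pitx2 itself, H3K27ac was lower in the deletion libraries. The region lay at chromosome 3, 129213656 to 129222296 (mm10), annotated to intron 3 of 3 of the transcript NM_001042504 with its centre 4044 bp from the start of the transcript NM_001287048. It held 116 ± 15.5 tags per 10000000 library tags in controls and 68.0 ± 26.2 in deletion libraries (SD, n = 2), 1.71-fold lower. Both deletion libraries (49.46 and 86.55) lay below both controls (127.18 and 105.24). The log2 fold change was -0.81 (SE 0.21), with an adjusted p of 0.0182 by limma over the 101 regions of the Pitx2 window alone and 0.432 over all regions. Under TMM factors, which take out the shift of the whole table, it was -0.95. None of the other 3 antibodies had a region past the threshold in its window of 127 (H3K4me1), 199 (H3K27me3) or 41 (CTCF) regions by limma, with 7, 8 and 0 regions at an unadjusted p under 0.05, nor by DESeq2, voom or edgeR. Without deletion replicate 2 the H3K27me3 window held 4 (1 higher and 3 lower), and without control replicate 1 the CTCF window held 26, all higher. The H3K27ac call ended without control replicate 1 (-0.68, adjusted p = 0.485), without control replicate 2 (-0.95, adjusted p = 0.737) and without deletion replicate 1 (-0.41, adjusted p = 0.766). No region of the window was at 0 in both deletion libraries for any antibody, so the tables did not show the deleted interval and do not check the genotype labels.

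Summed over its regions, Pitx2 carried 122 ± 13.9 tags of H3K27ac in controls and 74.1 ± 26.5 in deletion libraries (SD, n = 2). That gene-level difference was -0.75 on the log2 scale (SE 0.23), or -0.92 relative to the median of all genes, and ranged from -1.12 to -0.38 without single libraries. It did not pass over all genes by limma (adjusted p = 0.860), and did with loess offsets (adjusted p = 0.00129), the DESeq2 Wald test (0.00811) and edgeR with TMM factors (0.0342). Pitx2 was otherwise alike between genotypes at this precision, at 133 ± 16.5 against 136 ± 3.22 tags of H3K4me1, 1194 ± 144 against 1280 ± 125 tags of H3K27me3 and 6.13 ± 3.76 against 5.46 ± 1.48 tags of CTCF. None of these passed by limma (adjusted p = 0.888, 1.00 and 0.945). For CTCF the log2 fold change was -0.05, or -0.57 relative to the median of all genes. The H3K27me3 signal came from a single domain at chromosome 3, 129178482 to 129236919, that covers the whole gene, and the CTCF signal from a single peak at 129204901 to 129205081. Enpep, the aminopeptidase gene beside Pitx2, held 68.9 ± 0.156 against 80.8 ± 5.65 tags of H3K27ac and 124 ± 8.20 against 129 ± 2.39 tags of H3K4me1. Neither passed (adjusted p = 0.860 and 0.839 by limma), and Enpep had no gene-level value in the other tables.

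**Figure D1:**
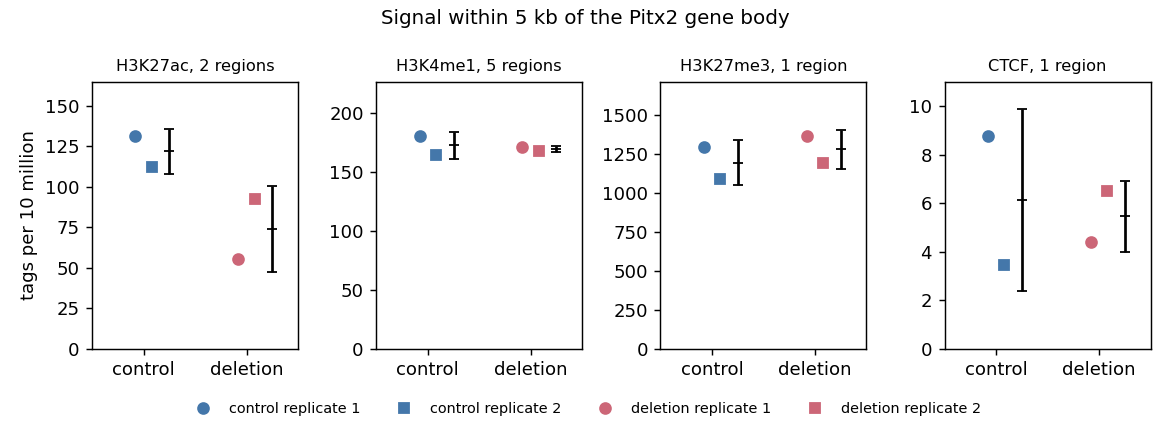
Signal within 5 kb of the Pitx2 gene body in tags per 10000000 library tags, 1 panel per antibody, with 1 point per library and the mean ± SD (n = 2) of each genotype as black bars. H3K27ac lies at 131.69 and 112.04 in controls and at 55.37 and 92.79 in deletion libraries, and the other 3 antibodies overlap between genotypes.

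Across the genome, the H3K27ac values with the lowest p came from genes of many kinds, 2 of them sarcomeric. Myl3, the ventricular myosin light chain, had 6.54 ± 0.955 tags in controls and 17.1 ± 0.849 in deletion libraries from a low region at -4819 bp from its start (chromosome 9, 110758212 to 110759513). Actn2, the sarcomeric actinin, had 169 ± 36.4 and 102 ± 46.3 (SD, n = 2). Golga7b, a palmitoylation partner, had 20.1 ± 0.0778 and 9.79 ± 0.233. Col7a1, the anchoring-fibril collagen, had 21.2 ± 1.97 and 11.8 ± 3.34, and Rfxank, a regulator of MHC class II genes, 23.4 ± 5.45 and 13.0 ± 0.474. Myadml2 had 33.2 ± 2.43 and 20.3 ± 11.1. Values were higher in deletion libraries at Mypop (18.4 ± 3.61 and 35.7 ± 0.375), Ube2a (11.5 ± 3.22 and 22.6 ± 1.66), Rnf219 (26.3 ± 0.453 and 47.5 ± 12.1), Rpp40 (10.5 ± 1.43 and 20.8 ± 1.44) and Abcc12 (15.6 ± 2.65 and 29.1 ± 6.34). None of these passed by limma over 16074 genes (lowest adjusted p = 0.198, Myl3). With loess offsets Myl3, Actn2, Golga7b, Col7a1, Rfxank and Myadml2 passed (adjusted p from 0.00137 to 0.0338), and by edgeR with TMM factors Golga7b did (0.0410).

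Among single H3K27ac regions, an intergenic region at chromosome 14, 55385211 to 55388798, held 74.6 ± 13.5 and 36.0 ± 2.25 tags. It lay at -91754 bp from the nearest start, that of Dhrs4, a retinal reductase gene. By limma its adjusted p was 0.239, and under TMM factors 0.00163 with a log2 fold change of -1.15. An intergenic region of chromosome 2, 107614322 to 107615334, held 13.7 ± 1.03 and 4.56 ± 2.62. It lay 324239 bp from the nearest start, that of Kcna4, a voltage-gated potassium channel gene. A region in intron 7 of 38 of Abcc8, the sulfonylurea receptor of ATP-sensitive potassium channels (chromosome 7, 46154622 to 46155257) held 9.27 ± 3.49 and 2.11 ± 0.354. A region at -9196 bp from the Abcc12 start (chromosome 8, 86575536 to 86576036) held 1.08 ± 0.0707 against 6.75 ± 0.240. An intergenic region at -140410 bp from the Pdzrn3 start, its nearest (chromosome 6, 101516747 to 101519868), held 20.3 ± 4.50 against 40.9 ± 1.53. The Kcna4 region passed with DESeq2 size factors (0.0382), loess offsets (0.01002), voom (0.0366) and without deletion replicate 2 (0.00637), and the Abcc8, Abcc12 and Pdzrn3 regions with loess offsets (0.0135, 0.0339 and 0.0333). By limma, 0 regions and 0 genes passed, with 6312 regions higher and 1896 lower at an unadjusted p under 0.05, and 694 genes higher and 131 lower. Other tools called 2 regions and 11 genes (DESeq2 Wald test), 41 and 1 (voom), 3 and 47 (edgeR with TMM factors), and loess offsets 225 and 146, of which 222 and 143 were lower in the deletion libraries. The median region lay 0.13 and the median gene 0.17 above 0 on the log2 scale under the deposited scaling. Without control replicate 1 these medians were 0.198 and 0.285, and without control replicate 2 they were 0.0336 and 0.0339, while the gene median was 0.104 without deletion replicate 2. TMM factors removed that shift. The regions under an unadjusted p of 0.05 then split into 2681 higher and 5073 lower, and the genes into 304 higher and 910 lower. Without deletion replicate 2, 14 regions passed, all lower.

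Gene lists of the contractile cell stood lowest in H3K27ac. Of the 27 measured genes of the sarcomere and Z-disc, 25 lay below the median of all genes and 2 above it, with a median of -0.47 relative to all genes. The list passed as lower with the preset correlation (camera adjusted p = 2.66e-20) and not with an estimated one (adjusted p = 0.583 with an estimated correlation). Over all genes 0 of its members passed by limma (1 higher and 8 lower at an unadjusted p under 0.05). Adjusted over the list alone, 1 was higher (Myl3, adjusted p = 3.3e-04) and 2 were lower, Actn2 (0.00858) and Actc1, the cardiac actin, at 33.7 ± 1.39 and 23.4 ± 15.4 tags (0.0449). For Actc1 the mean ± SD of the deletion libraries overlapped that of the controls. Actn2 held 69.38 tags in deletion replicate 1 and 134.8 in deletion replicate 2, against 194.82 and 143.35 in controls. Xirp1, an actin-binding protein of intercalated discs, had 142 ± 31.4 and 93.8 ± 30.4 tags. The list scored -0.66 in deletion replicate 1 and -0.25 in deletion replicate 2, relative to all genes and the control mean. Deletion replicate 1 also had the lowest share of tags on chromosome Y and, for the 3 histone marks, in mitochondrial regions.

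Ion channel and calcium genes lay on the same side in H3K27ac. The conduction and ion channel list (28 genes, median -0.42 relative to all genes, camera adjusted p = 1.91e-12, adjusted p = 0.583 with an estimated correlation) included Kcnj11, the pore of ATP-sensitive potassium channels, at 91.9 ± 16.1 and 66.9 ± 22.3 tags, and Kcnj5, a subunit of the acetylcholine-activated channel, at 191 ± 22.3 and 140 ± 42.1 (SD, n = 2). It also held Kcnh2, the rapid delayed rectifier, at 257 ± 28.5 and 187 ± 53.9, and Kcnj3, the partner of Kcnj5, at 170 ± 44.7 and 128 ± 60.8. The calcium handling list (17 genes, -0.24, camera adjusted p = 6.17e-08, adjusted p = 0.583 with an estimated correlation) included Trdn, the triadin of the release complex (234 ± 54.0 and 153 ± 58.9), and Slc8a1, the sodium-calcium exchanger (261 ± 44.4 and 191 ± 51.1). Its other leading members were Sln, the calcium pump inhibitor sarcolipin (175 ± 28.2 and 133 ± 40.6), and Ryr2, the release channel (143 ± 17.2 and 112 ± 39.4). No member of either passed over all genes or adjusted over the list alone by limma, and 5 and 2 were lower at an unadjusted p under 0.05. The mean ± SD of each gene given here overlapped between genotypes. Relative to all genes and the control mean, ion channels scored -0.56 in deletion replicate 1 and -0.28 in deletion replicate 2. Calcium handling scored -0.42 and -0.15 in the same order.

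Genes tied to atrial identity and atrial fibrillation shared this direction. Of 19 atrial genes, 17 lay below the median of all genes (median -0.33, camera adjusted p = 6.8e-11, adjusted p = 0.583 with an estimated correlation). Among them were Nppa, the atrial natriuretic peptide (66.2 ± 12.01 and 43.5 ± 10.4 tags), Mybphl, an atrial myosin-binding protein (136 ± 2.47 and 99.8 ± 28.9), Kcnj5 and Fgf12, a modulator of sodium channels (104 ± 31.0 and 75.5 ± 26.1). Genes near atrial fibrillation risk variants (34, median -0.19, camera adjusted p = 4.03e-08, adjusted p = 0.583 with an estimated correlation) were led by Pitx2 and Nkx2-5, the cardiac homeobox factor (331 ± 52.3 and 220 ± 125), followed by Rpl3l, a muscle ribosomal protein (28.9 ± 5.97 and 19.2 ± 5.24). Cardiac transcription factors (20, median -0.26, camera adjusted p = 3.09e-06, adjusted p = 0.583 with an estimated correlation) included Myocd, the myocardin coactivator (296 ± 35.1 and 212 ± 87.6), Esrrb (8.34 ± 1.90 and 5.82 ± 1.32) and Prox1 (85.6 ± 18.0 and 71.3 ± 21.6). Over all genes 0 members of these lists passed by limma, with 5, 5 and 2 lower at an unadjusted p under 0.05, and adjusted over the list alone only Pitx2 did (0.0307 in the risk list). The mean ± SD overlapped between genotypes for several of them, Nkx2-5, Myocd and Prox1 included. In deletion replicates 1 and 2, atrial genes scored -0.54 and -0.20 relative to all genes and the control mean. Risk genes scored -0.23 and -0.14, and cardiac transcription factors -0.29 and -0.16.

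Metabolic and stress lists also passed as lower in H3K27ac with the preset correlation. Fatty acid oxidation (26 genes, median -0.23, camera adjusted p = 7.31e-07, adjusted p = 0.661 with an estimated correlation) included Ppargc1a, the coactivator of mitochondrial genes, at 62.9 ± 7.38 and 39.99 ± 13.8 tags. On the other side lay Acads, a short-chain acyl dehydrogenase, at 29.7 ± 4.94 and 44.5 ± 11.8. Acadm (172 ± 28.7 and 134 ± 44.9) and Ppara, the fatty acid receptor (79.1 ± 1.48 and 61.4 ± 12.1), were the next by p. Cardiac stress genes (17, median -0.27, camera adjusted p = 7.31e-07, adjusted p = 0.583 with an estimated correlation) included Nppa, Xirp2 (73.0 ± 30.1 and 48.3 ± 16.2) and Nppb, the ventricular natriuretic peptide (35.9 ± 13.3 and 24.7 ± 6.54). Immediate early genes (22, median -0.22, camera adjusted p = 8.3e-04, adjusted p = 0.803 with an estimated correlation) included Dusp1 (280 ± 58.0 and 235 ± 64.7), Nr4a1 (128 ± 30.6 and 109 ± 27.5) and Fos (109 ± 30.4 and 91.9 ± 23.5). Immune markers (21, median -0.18), developmental Polycomb targets (7, median -0.20) and skeletal muscle markers (7, median -0.14) passed with camera adjusted p of 0.00894, 0.00894 and 0.0304, and each had an adjusted p of 0.583 with an estimated correlation. Their lowest p belonged to Cd68, the macrophage marker, which went the other way (5.21 ± 1.24 and 10.3 ± 0.714), Pitx2 and Atp2a1, the skeletal calcium pump (76.2 ± 6.71 and 59.6 ± 15.7). No member of these 6 lists passed over all genes by limma, with 2, 3, 0, 3, 1 and 0 of them at an unadjusted p under 0.05 in the order named, and adjusted over the list alone only Pitx2 did (0.00632). In deletion replicates 1 and 2, fatty acid oxidation scored -0.40 and -0.09, stress genes -0.42 and -0.20 and immediate early genes -0.35 and -0.07. Immune markers scored -0.15 and -0.08, Polycomb targets -0.25 and 0.07 and skeletal muscle markers -0.13 and -0.27.

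The other 12 lists did not pass in H3K27ac. Markers of fibroblasts (23 genes, median 0.05 relative to all genes, camera adjusted p = 0.182) and of endothelium (21, median 0.04, 0.187) lay slightly above all genes, and those of mural cells at it (15, median -0.00, 0.265). Ventricular genes had an adjusted p of 0.297, the electron transport chain 0.115, the antioxidant response 0.355, the left-right pathway 0.115, Hox genes 0.845, epicardial markers 0.840, adipocyte markers 0.474, neural and Schwann cell markers 0.265 and the neighbours of Pitx2 0.397. The electron transport chain passed as lower with TMM factors (0.0344), at a gene distance of 2 kb (0.0256), without control replicate 2 (0.0238) and without deletion replicate 2 (0.0151). Epicardial markers passed as higher at 2 kb (0.0438), against the direction at 10 kb, and neural and Schwann cell markers as lower at 50 kb (0.00761). Without deletion replicate 1, 6 lists passed, those of the sarcomere (4.8e-04), ion channels (0.00113), atrial genes (0.0279), risk genes (0.0146), stress genes (0.0146) and immune markers (0.00798), and calcium handling did not (0.0585), nor did fatty acid oxidation (0.242), cardiac transcription factors (0.0888), immediate early genes (0.484), Polycomb targets (0.253) or skeletal muscle markers (0.0888). Immediate early genes also lost the call without control replicate 1 (0.178), immune markers without control replicate 2 (0.230) and without deletion replicate 2 (0.191). Skeletal muscle markers lost it without any 1 of the 4 libraries (0.104 without control replicate 1, 0.0605 without control replicate 2 and 0.118 without deletion replicate 2). With TMM factors, Polycomb targets and skeletal muscle markers had an adjusted p of 0.0766 and immune markers 0.0997. Gene distances also ended calls, for Polycomb targets at 2 kb (0.483) and 50 kb (0.327), immune markers at 50 kb (0.141) and skeletal muscle markers at 2 kb (0.0815).

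**Figure D2:**
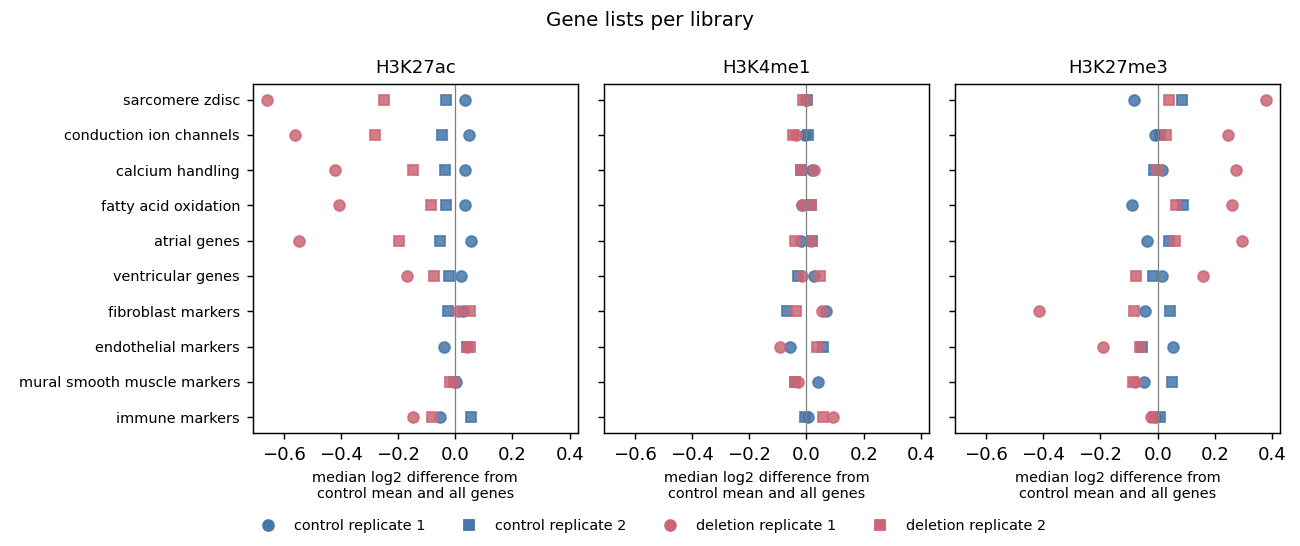
Median log2 difference of 10 gene lists in each library, relative to the mean of the controls and to the median of all genes, for the 3 histone marks, with 1 point per library. In H3K27ac the sarcomere list lies at -0.66 in deletion replicate 1 and -0.25 in deletion replicate 2, and in H3K4me1 at -0.00 and -0.01.

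In H3K4me1, 17 regions were higher and 22 lower in the deletion libraries by limma, of 126153 tested. The lowest p belonged to chromosome X, 169978805 to 169983302, in intron 4 of 9 of Mid1, which encodes a microtubule-bound ubiquitin ligase, where signal fell from 135 ± 17.2 to 59.4 ± 1.56 tags (SD, n = 2; log2 -1.17, adjusted p = 1.2e-10). Near Syn2, which encodes a synaptic vesicle protein, chromosome 6, 115237675 to 115242695 rose from 49.3 ± 1.65 to 95.0 ± 9.07 (log2 0.93, adjusted p = 7.1e-06). By Fam25c, chromosome 14, 34354356 to 34355789 fell from 27.3 ± 2.85 to 8.82 ± 1.56 (log2 -1.53, adjusted p = 8.0e-05). A long domain over Raf1, the kinase of the MAP kinase cascade (chromosome 6, 115639710 to 115679004), rose from 733 ± 10.5 to 860 ± 9.14 (log2 0.23, adjusted p = 0.00468). Its call ended without control replicate 1 (adjusted p = 0.148) and without control replicate 2 (0.0534). It was also lost under TMM factors (log2 0.17, adjusted p = 1.00), DESeq2 size factors, loess offsets, voom, the DESeq2 Wald test and edgeR with TMM factors. The region at chromosome 14, 119831660 to 119835636 rose from 37.5 ± 6.89 to 68.7 ± 3.19 (log2 0.87, adjusted p = 6.3e-04), and its call ended without control replicate 2 (0.177). A mitochondrial region, 10889 to 16299, was lower at 5971 ± 1137 against 3738 ± 1980 (log2 -0.77, adjusted p = 8.0e-05), and its value in deletion replicate 1 was the lowest. Without that library its log2 fold change was -0.20, still past the threshold. The call was lost by the DESeq2 Wald test, by edgeR with and without TMM factors (adjusted p = 0.945 without) and with a robust variance prior (0.936).

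Of the changed H3K4me1 regions, 9 lay on chromosome 14, 8 on chromosome 2, 6 on chromosome 6 and 3 each on chromosomes 9, 13 and X. A further 2 each lay on chromosome 1 and the mitochondrial genome, and 1 each lay on chromosomes 11, 17 and Y. All those on chromosomes 9 (3), X (3), Y (1) and the mitochondrial genome (2) were among the 22 lower ones. So were the regions of high signal at chromosome 2, 98662171 to 98664258 and 98666219 to 98667530. At chromosome 9, 35304771 to 35305908, control replicate 1 (857.15) lay below deletion replicate 2 (861.82). At 123 to 6698 of the mitochondrial genome, control replicate 2 (5808.87) did (5876.69). A lower region at chromosome 1, 24612538 to 24613296, held 28.38 and 67.88 tags in deletion replicates 1 and 2, against 81.67 and 75.45 in controls. Whether such regions hold repeats was not tested. The window from 30 to 35 Mb of chromosome 14 held 5 of the changed regions, that of Fam25c among them. The window from 115 to 120 Mb of chromosome 6 held 3, the Syn2 and Raf1 regions among them. Without control replicate 2 the count was 19, and without deletion replicate 2 it was 142. TMM factors gave 7 higher and 31 lower, and split the regions under an unadjusted p of 0.05 into 2660 higher and 2713 lower, against 6267 and 1298 under the deposited scaling.

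**Figure D3:**
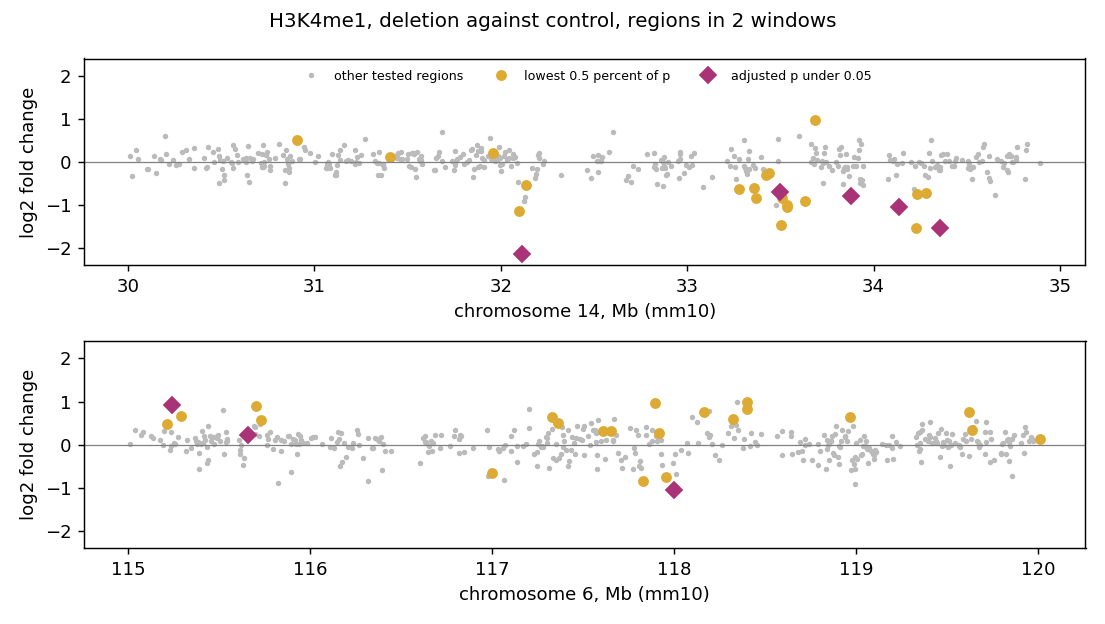
Log2 fold change of H3K4me1 (deletion minus control) of each tested region against its position in Mb (mm10) from 30 to 35 Mb of chromosome 14 (top) and from 115 to 120 Mb of chromosome 6 (bottom). Coloured points are regions in the lowest 0.5% of p and diamonds those past an adjusted p of 0.05, with 20 of 24 coloured regions below 0 in the top panel and 20 of 24 above 0 in the bottom panel.

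At gene level, H3K4me1 rose at Syn2 (118 ± 3.55 to 165 ± 10.5 tags; log2 0.48, adjusted p = 0.0280), of 17414 genes tested by limma. It fell at Mapk8, which encodes the stress kinase JNK1 (660 ± 40.02 to 549 ± 2.47, log2 -0.27, adjusted p = 0.0446). Syn2 lies in the chromosome 6 window named above, and Mapk8, Fam25c and Msmb lie in the chromosome 14 window. A segment of another mouse strain in these windows cannot be told apart from an effect of the deletion. The Syn2 call ended without control replicate 1 (0.0797), without deletion replicate 1 (0.411), with loess offsets (0.0554), by the DESeq2 Wald test (0.507) and at a gene distance of 50 kb (0.129). The Mapk8 call ended without control replicate 1 (0.286), without deletion replicate 1 (0.170) and without deletion replicate 2 (0.0658). It also ended by edgeR without TMM factors (0.0620) and at gene distances of 2 kb (0.891) and 50 kb (0.433). The third gene past the threshold was the unnamed model G530011O06Rik by the X region (192 ± 14.7 to 80.1 ± 2.45, adjusted p = 7.9e-10), named after its values were seen. It was not among the passing genes at a gene distance of 2 kb, where the 1 lower gene was Fam25c. The coat colour gene agouti, whose symbol is a, had 53.9 ± 3.09 and 30.5 ± 18.97 tags, and Msmb, a secreted prostate protein, 47.5 ± 6.40 and 31.2 ± 7.25. Raet1e, a ligand of the NKG2D receptor, had 57.0 ± 5.18 and 39.9 ± 9.14, Fam25c 95.9 ± 3.61 and 76.9 ± 9.86, and Sdsl 12.3 ± 1.95 and 6.90 ± 0.262. Hnrnpf, a splicing factor, had 336 ± 11.5 and 405 ± 3.35, and Cass4, a focal adhesion scaffold, 30.6 ± 9.53 and 51.1 ± 2.404. Frmd4b had 802 ± 29.1 and 909 ± 13.2, Lbp, the lipopolysaccharide-binding protein, 132 ± 10.7 and 171 ± 15.2, and the protocadherin Pcdhgc5 1002 ± 29.5 and 1124 ± 12.6. None of these passed by limma (adjusted p from 0.171 to 0.383). Agouti passed by voom (0.0201), and without control replicate 1 (0.0497), control replicate 2 (0.00177) or deletion replicate 2 (1.2e-06), and Cass4 without control replicate 2 (1.2e-04). At a gene distance of 2 kb, Hnrnpf (0.0413), Cass4 (1.6e-04), Lbp (0.00294) and Fam25c (5.1e-07) passed. Without control replicate 2, without deletion replicate 1 and without deletion replicate 2 the number of genes was 6, 1 and 7. Among 24 lists, only immediate early genes passed, as higher (22 genes, median 0.04 relative to all genes, camera adjusted p = 0.0182, adjusted p = 0.974 with an estimated correlation, 0.165 with TMM factors). The adjusted p of this list was 0.529 without control replicate 2, 0.0691 without deletion replicate 1, 0.144 without deletion replicate 2 and 0.290 at a gene distance of 2 kb. Of the immediate early genes Zfp36, which destabilises cytokine messages, had 89.8 ± 1.54 and 112 ± 5.78 tags, Nr4a3 132 ± 9.50 and 155 ± 6.26, Junb 43.5 ± 4.88 and 55.0 ± 0.502 and Klf2 252 ± 13.3 and 281 ± 2.02. By limma 0 of them passed over all genes and 0 adjusted over the list alone, and 7 were higher at an unadjusted p under 0.05. Fibroblast markers (adjusted p = 0.412) passed as higher at 50 kb (0.00977), without control replicate 1 (2.4e-04) and without deletion replicate 2 (0.00457). The sarcomere list, lowest in H3K27ac, had a median of -0.02 in H3K4me1 (adjusted p = 0.649).

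In H3K27me3, lists of heart muscle genes lay above all genes and lists of stromal and vascular genes below. Genes of the sarcomere (18, median 0.20 relative to all genes, camera adjusted p = 0.0140), ion channels (30, 0.18, 0.00395), atrial genes (16, 0.19, 0.0281), risk genes (23, 0.16, 0.00184) and cardiac transcription factors (18, 0.15, 0.0204) passed as higher, each with an adjusted p of 0.776 with an estimated correlation. Markers of fibroblasts (19, -0.21, 8.2e-04) and endothelium (14, -0.11, 0.0140) passed as lower. Each of these 7 lists had an adjusted p of 0.776 with an estimated correlation and 0.797 without deletion replicate 1. Without control replicate 1 the adjusted p was 0.167 for the sarcomere list and endothelial markers and 0.138 for atrial genes. Cardiac transcription factors lost the call without control replicate 2 (0.0629) and without deletion replicate 2 (0.198), and atrial genes without deletion replicate 2 (0.0711). With TMM factors both of these had an adjusted p of 0.0590, and at a gene distance of 2 kb only 1 list, that of atrial genes, passed (adjusted p = 0.0134). The sarcomere list scored 0.38 in deletion replicate 1 and 0.04 in deletion replicate 2, and fibroblast markers scored -0.41 and -0.08. Obscn, the giant obscurin of the sarcomere, had 140 ± 2.96 and 176 ± 32.9 tags, Myh6, the alpha myosin heavy chain, 34.2 ± 5.95 and 46.8 ± 10.0, and Kcnj11 152 ± 2.92 and 200 ± 55.3. Nr2f1, an atrial nuclear receptor, had 123 ± 22.3 and 159 ± 24.5, and Hand2, a heart basic helix-loop-helix factor, 7.09 ± 1.59 and 13.7 ± 2.36. Fbln2, a fibroblast matrix protein, had 65.3 ± 0.594 and 50.2 ± 10.2, Col6a3 68.2 ± 1.15 and 52.1 ± 14.4. Fli1, an endothelial ETS factor, had 105 ± 13.8 and 72.4 ± 16.4, and Tie1, an endothelial receptor kinase, 59.2 ± 11.2 and 44.2 ± 11.6. No member of the 7 lists passed over all genes or adjusted over the list alone by limma. The other 17 tested lists, the Hox genes (adjusted p = 0.925) and the developmental Polycomb targets (0.925) among them, did not pass. These 2 passed as higher without control replicate 1 (0.0128 and 0.01005) and as lower without control replicate 2 (0.00839 and 0.00772). Fatty acid oxidation passed as higher without control replicate 2 (0.00839) and the electron transport chain as higher at 50 kb (0.0354).

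Among single H3K27me3 regions and genes, 0 regions and 1 gene passed by limma. The largest region-level difference by p was at Olfr212, an olfactory receptor gene, at chromosome 6, 116515280 to 116520254 in its 3' UTR, with 83.5 ± 0.453 and 39.7 ± 0.0283 tags (log2 -1.05, adjusted p = 1.00 by limma). It was followed by chromosome X, 169982019 to 169983037 (15.1 ± 0.198 and 3.31 ± 1.07) and a second region by Olfr212 at 116522677 to 116523669 (15.6 ± 1.15 and 4.27 ± 0.361). These 3 regions passed without deletion replicate 1 (adjusted p from 1.8e-04 to 4.7e-04) and without deletion replicate 2 (from 4.7e-06 to 3.3e-04). On the other side stood Sfi1, a centrosome protein gene (chromosome 11, 3184052 to 3200227; 1040 ± 29.3 and 1563 ± 210.5). So did Arhgap22 (chromosome 14, 33251361 to 33254318, 11.5 ± 0.0424 and 29.2 ± 7.27) and chromosome 6, 117776670 to 117781553 (28.6 ± 3.85 and 58.1 ± 13.6). The Olfr212 regions and that at 117776670 lie in the window from 115 to 120 Mb of chromosome 6 named for H3K4me1. The Arhgap22 region lies in the chromosome 14 window, from 30 to 35 Mb. Without deletion replicate 1 the Arhgap22 region (6.4e-05) and that of chromosome 6 (5.4e-05) passed, and without deletion replicate 2 the Arhgap22 region did (0.0422). By limma 0 of 97610 regions passed, with 1668 higher and 1744 lower at an unadjusted p under 0.05, while the DESeq2 Wald test and voom called 1 each and edgeR with TMM factors 0. The single gene past the threshold was G530011O06Rik, chosen after its values were seen, which fell from 49.5 ± 4.91 to 13.6 ± 3.77 (log2 -1.81, adjusted p = 0.0108). Raet1a and Raet1d, which like Raet1e encode NKG2D ligands, had 1367 ± 97.6 and 882 ± 125 and 238 ± 10.8 and 162 ± 32.2 tags. Nrg3, a neuregulin, had 200 ± 12.04 and 136 ± 1.30, Cd200, an inhibitory surface protein, 30.9 ± 5.91 and 16.4 ± 3.05, Thoc7 31.7 ± 4.19 and 16.6 ± 5.93, and Rhog, a small GTPase, 42.0 ± 0.382 and 23.6 ± 10.7. Ccl28, a chemokine, had 169 ± 10.9 and 258 ± 16.3, Oas1f 80.7 ± 11.9 and 118 ± 13.8, and Tsnax 7.22 ± 0.332 and 15.6 ± 4.19. Inip had 13.8 ± 0.990 and 24.6 ± 0.269, and Psg21 14.8 ± 2.85 and 26.2 ± 1.97, none passing by limma. Raet1a passed by the DESeq2 Wald test (adjusted p = 3.3e-11), by edgeR without TMM factors (0.00142), with a robust variance prior (2.3e-04) and at a gene distance of 2 kb (0.0360), and Ccl28 by edgeR without TMM factors (0.0488). The Sfi1 gene, on the higher side, passed in the same 4 settings as Raet1a (1.0e-05, 0.00572, 0.00144 and 0.0483). Raet1d passed without deletion replicate 1 (0.00171), and Ccl28, Oas1f, Tsnax, Cd200, Thoc7 and Rhog without deletion replicate 2 (adjusted p from 3.7e-06 to 0.0163). Counts moved with single libraries: 713 regions and 176 genes passed without deletion replicate 1, 1432 and 410 without deletion replicate 2, and 0 genes without control replicate 1 or control replicate 2. The call of G530011O06Rik ended with TMM factors, DESeq2 size factors, loess offsets, voom and edgeR with TMM factors, each giving 0 genes. It was also absent at gene distances of 50 kb, with 0 genes, and 2 kb, where Raet1a and Sfi1 were the genes that passed.

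CTCF values of deletion libraries lay above those of controls by a median of 0.52 over all peaks on the log2 scale under the deposited scaling. That median was 0.934 without control replicate 1 and 0.0827 without control replicate 2, and control replicate 2 had the lowest share of tags in peaks (3.15%). Single peaks stood apart from that shift near the T cell receptor locus of chromosome 14. A peak at 53045419 to 53045599 had 0.390 ± 0.552 and 6.28 ± 1.80 tags (SD, n = 2; log2 2.43) and a peak at 53505351 to 53505531 had 1.79 ± 0.346 and 13.0 ± 0.566 (log2 2.33). In intron 3 of 3 of Dydc2, chromosome 14, 41053179 to 41053359 had 13.5 ± 6.13 and 1.45 ± 0.629 (log2 -2.53). These peaks had adjusted p of 0.0535, 0.154 and 0.0535 by limma. Under TMM factors their log2 fold changes were 2.23, 1.85 and -2.93 (adjusted p = 0.0457, 0.0147 and 2.1e-06). Peaks at chromosome X, 169972776 to 169972956 in an intron of Mid1 (6.33 ± 2.02 and 1.13 ± 0.106), chromosome 6, 101642967 to 101643147 (7.74 ± 6.62 and 1.89 ± 2.38) and chromosome 4, 126627076 to 126627256 (2.3 ± 2.97 and 7.79 ± 0.332) had an adjusted p of 0.741. The Mid1 peak passed under TMM factors (log2 -2.15, adjusted p = 0.0138), DESeq2 size factors (0.0142), loess offsets (0.0245), voom (0.0285) and edgeR with TMM factors (0.00192), and the chromosome 6 peak by voom (0.0219). Without control replicate 1 all of these peaks but that of chromosome 6 passed (adjusted p from 8.4e-07 to 0.0204). Without control replicate 2 the peak at 53505351 (1.7e-04), the Dydc2 peak (1.1e-04) and the chromosome 6 peak (0.0135) did. By limma 0 of 31150 peaks passed (501 higher and 10 lower at an unadjusted p under 0.05). With TMM factors this unadjusted split was 827 higher and 896 lower. The DESeq2 Wald test called 5, and calls were 32 by voom, 21 by edgeR with TMM factors and 22 by limma with TMM factors, 3 higher and 19 lower. Without control replicate 1 the count was 19453, of which 19433 were higher, and without control replicate 2 it was 6.

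Among genes, the protocadherin Pcdhb6 had 3.5 ± 0.905 and 14.1 ± 2.45 tags of CTCF, Wrap73 1.52 ± 0.417 and 7.27 ± 0.785, and Efcab2 4.77 ± 3.86 and 15.5 ± 4.72. Elmsan1 had 1.21 ± 0.601 and 5.91 ± 2.71, Kmt5b, a histone H4 methyltransferase, 7.59 ± 7.55 and 20.4 ± 9.21, and Zfp317 1.88 ± 0.636 and 7.54 ± 3.25. Frg2f1 had 6.29 ± 2.82 and 2.88 ± 0.0919, Mroh3 8.16 ± 3.46 and 4.50 ± 1.01, and Fbxo10 6.05 ± 2.79 and 3.28 ± 0.474. Abracl had 4.07 ± 0.841 and 2.24 ± 1.09, Wdr76 4.09 ± 1.16 and 2.26 ± 0.0707 and C1galt1c1, a chaperone of glycosylation, 3.62 ± 0.368 and 2.05 ± 0.516. None of them passed by limma (adjusted p = 0.719 for each), nor did any of the 9899 genes. At an unadjusted p under 0.05, 208 were higher and 0 lower under the deposited scaling, and 256 and 263 with TMM factors. The number of passing genes was 2 by the DESeq2 Wald test, 5 by voom and 5 by edgeR with TMM factors. Without control replicate 1 the count was 5958 genes, the 6 named on the higher side among them (adjusted p from 3.9e-08 to 0.0186), and without control replicate 2 it was 2. None of 23 lists passed in CTCF (lowest camera adjusted p = 0.261, immediate early genes).

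Regions on chromosome 3, which carries the deletion, were no more often changed than those of other autosomes. Outside the Pitx2 window, 0 of 6723 H3K4me1 regions on chromosome 3 passed against 33 of 116290 elsewhere (odds ratio 0, 95% interval up to 2.05, Fisher's exact p = 0.260). No H3K27ac, H3K27me3 or CTCF region passed by limma on any autosome, so no such ratio could be formed. At an unadjusted p under 0.05 the odds ratios were 0.976 for H3K27ac, 0.931 for H3K4me1, 1.01 for H3K27me3 and 0.973 for CTCF (Fisher's exact p = 0.667, 0.194, 0.834 and 1, and regions are not independent replicates).

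Fold changes of overlapping regions were weakly related between antibodies. Across regions, which are not independent replicates, Pearson's r was 0.0945 and Spearman's rho 0.0888 between H3K27ac and H3K4me1 (110109 pairs), and -0.123 and -0.140 between H3K27ac and H3K27me3 (16729 pairs). The other 4 of the 6 pairs of antibodies had r of 0.0619 (H3K27ac and CTCF), -0.0473 (H3K4me1 and H3K27me3), 0.0236 (H3K4me1 and CTCF) and 0.00747 (H3K27me3 and CTCF). In the upper 50 percent of abundance of both antibodies, r of H3K27ac with H3K27me3 was -0.265 and with CTCF 0.172.

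The share of signal on the sex chromosomes set deletion replicate 1 apart. Chromosome Y held 0.00793% of its H3K27ac signal against 0.0158, 0.0194 and 0.0175% in control replicate 1, control replicate 2 and deletion replicate 2, and 0.00461% of its H3K4me1 signal against 0.0103, 0.0108 and 0.0108%. For H3K27me3 the values were 0.0134% against 0.0270, 0.0326 and 0.0373%, and for CTCF 0.105% against 0.212, 0.220 and 0.202%. Chromosome X held 3.05% of the H3K27me3 signal of deletion replicate 1, against 1.85, 1.98 and 1.07%. In this share deletion replicate 2 also lay outside the controls, on the opposite side. The mitochondrial share was also lowest in deletion replicate 1, at 0.182% of H3K27ac tags against 0.616, 0.358 and 0.294% in the same order.

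**Figure D4:**
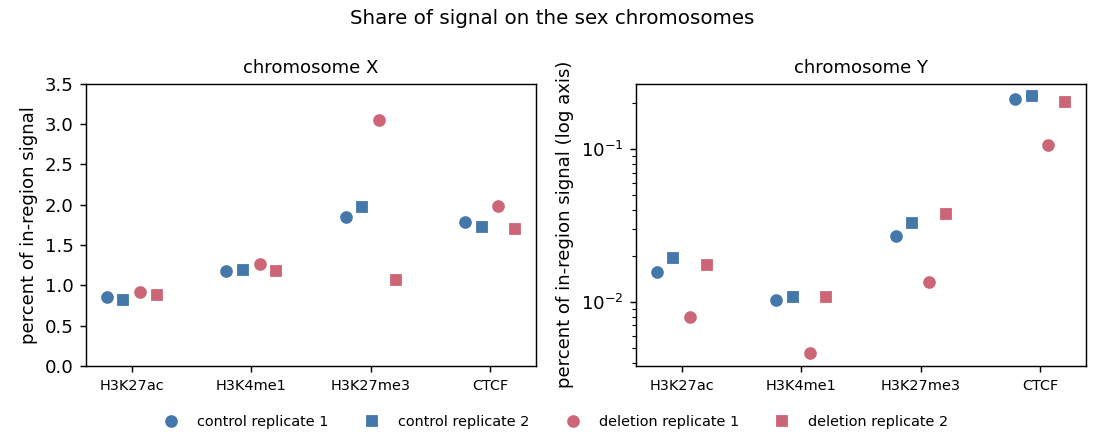
Percent of the signal in regions that lies on chromosome X (left) and chromosome Y (right, log axis) for each antibody, with 1 point per library. Deletion replicate 1 has the lowest Y share for all 4 antibodies and the highest H3K27me3 share on X, 3.05%.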

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

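The tests of female chromatin, enrichment, a strain segment, scaling and the share of cardiomyocytes below were chosen only after the result was seen, and those of copy number, chance position and atrial tissue before. Groups of 2 libraries were too small for a test of outlying libraries.

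Deletion replicate 1 had the lowest share of signal on chromosome Y, at 0.503, 0.448, 0.498 and 0.522 times the lowest other library for H3K27ac, H3K4me1, H3K27me3 and CTCF. Lower enrichment was argued against, since its share of tags in regions was at least 1.03 times that of the lowest other library, and so was genotype as the whole cause, since deletion replicate 2 had a Y share of 0.0175% in H3K27ac against 0.0158 and 0.0194% in controls and the lowest H3K27me3 share on X (1.07%). More chromatin from female mice in this library is a candidate explanation, as a hypothesis: its Y share was at most 0.522 times that of any other library, and H3K27me3, which coats an inactive X, put 3.05% of its signal on X against at most 1.98% elsewhere. Xist carried 39.36 tags of H3K4me1 in it against 21.19, 24.37 and 12.39 in control replicate 1, control replicate 2 and deletion replicate 2, and Ddx3y carried 15.87 tags of H3K27ac against 38.78, 31.51 and 53.48. In these values of both genes and in the H3K27me3 share on X, the controls lay between deletion replicates 1 and 2. The labels give no sex for any library, so the explanation stays open.

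Low-p H3K4me1 regions gathered in the windows from 30 to 35 Mb of chromosome 14 and from 115 to 120 Mb of chromosome 6, with 24 of the 631 regions in the lowest 0.5% of p in each, where even spacing gave 2.09 and 2.24; the same windows held 17 and 9 low-p regions of H3K27me3 (1.61 and 1.31 by even spacing), 4 and 9 of H3K27ac (2.28 and 2.46) and 3 and 3 of CTCF (0.561 and 0.441). A chance position of H3K4me1 regions taken singly was argued against, since the fullest window of any of 200 random draws held 11. The draws did not model neighbouring regions that vary together. A copy number difference over a whole window was argued against as well. The median of all regions of a window lay at most 0.172 from that of all tested regions over the 4 antibodies, with both signs across antibodies. A gain or loss over part of a window was not tested, since 24 low-p regions among 418 and 447 would barely move that median. A segment of another mouse strain in 1 genotype cannot be told apart from an effect of the deletion on distant chromatin, since 20 of the 24 regions in the chromosome 6 window were higher and 4 lower, against 4 and 20 in the chromosome 14 window, where 16 of the 17 H3K27me3 regions were higher, and the tables hold no alleles. An effect of the deletion on these windows stays open as an untested hypothesis. Other windows held fewer low-p H3K4me1 regions. The 11 of the draws is the highest count of any window. It therefore cannot tell whether a window with fewer tested regions held more than chance would place there. On chromosome 6 these other windows were 100 to 105 Mb (10 of 167 tested, 10 higher), 95 to 100 Mb (9 of 303, 4 higher) and 105 to 110 Mb (8 of 105, 7 higher). Next came 50 to 55 Mb of chromosome 14 and 165 to 170 Mb of chromosome 2, with 7 each. No cause was tested for them.

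H3K27ac in a region at an internal start of Pitx2 was lower in both deletion libraries. The shift of the whole H3K27ac table went the other way, with the median region 0.13 above 0 under the deposited scaling. Removing that shift with TMM factors could only lower the log2 fold change, which was then -0.95. This was therefore no independent test of scaling to library totals. Atrial tissue in the control pieces cannot be told apart from an effect of the deletion, since the atrial genes lay -0.33 from all genes, between the bounds set beforehand, and the sarcomere list lay lower still at -0.47. Fewer cardiomyocytes in deletion replicate 1 cannot be told apart from it either: the sarcomere list stood at -0.66 in H3K27ac and 0.38 in H3K27me3 of that library, yet at -0.000693 in H3K4me1, so the 3 marks do not decide together. Loss of H3K27ac through the deleted enhancer stays open as an untested hypothesis.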

How the results depend on the processing

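The TMM, edgeR, pseudocount, robust prior and stricter filter settings, and the gene lists without each library, were chosen only after the result was seen. The designs hold 2 libraries per genotype, and a fit without 1 of them assumes that the lone library varies like the other group. With no scaling factors the fit is the same by construction and has no value of its own. Without a filter the H3K27ac and H3K4me1 fits were also the same, since the filter had removed nothing. These are still counted as alike below. Results that passed neither by limma nor in the other setting are counted as staying on their side. Of the results for single genes, regions and lists, 1286 stayed on their side of the threshold and kept their direction across settings, 107 newly passed, 108 no longer passed and 8 changed direction. For the counts, Pitx2 values and correlations these were 243 alike, 93 moved by more than 1.5 times or the spread, 3 newly passing, 4 no longer passing and 11 changed in direction. Low CTCF values limit the folds of single peaks, and the cause of the differences below was not tested.

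The shared replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated at -0.0538 for H3K27ac, 0.0543 for H3K4me1, -0.0679 for H3K27me3 and 0.00540 for CTCF. With a replicate block the counts were 0 in the Pitx2 window of H3K27ac (region at an internal start of Pitx2 -0.81, adjusted p = 0.315), 180 H3K4me1 regions (141 higher and 39 lower) and 89 genes (83 and 6), 2 H3K27me3 regions and 3 genes, and 3 CTCF regions and 3 genes.

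For H3K27ac regions (0 by limma), DESeq2 size factors gave 13, loess offsets 225, the DESeq2 Wald test 2, voom 41, TMM factors 5 and edgeR with TMM factors 3, of which all but 3 (loess) were lower, and leaving out single libraries gave 0 to 14. For H3K27ac genes (0 by limma), size factors, voom, TMM factors and the 50 kb distance gave 1 each, loess offsets 146, the Wald test 11 and edgeR with TMM factors 47, and leaving out single libraries 0 to 0. The Pitx2 gene (-0.75) was -0.91 with loess offsets, -0.90 by the Wald test and -0.90 by edgeR with TMM factors, passing in each, and ranged from -1.12 to -0.38 without single libraries. The Pitx2 window held 0 to 1 regions without single libraries, and the region at the internal start ranged from -1.21 to -0.41. The count of passing H3K27ac lists (12) was 0 with an estimated correlation and 0 by fry, where the immune markers changed direction (adjusted p = 0.971), and 6 to 11 without single libraries, not always of the same lists.

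For H3K4me1 regions (39), the Wald test gave 8, edgeR without TMM factors 19 and single libraries left out 19 to 142. For H3K4me1 genes (3), voom and the 2 kb distance gave 5 each, the 50 kb distance 1 and single libraries left out 1 to 7. The Pitx2 gene (0.04) changed sign in most scalings, at -0.0356 with size factors, -0.0364 with loess offsets, -0.0368 by the Wald test, -0.0265 by voom, -0.0350 with TMM factors, -0.0344 by edgeR with TMM factors and -0.0420 at 50 kb, and from -0.0825 (without control replicate 2) to 0.17 without single libraries. Enpep (0.06) did likewise at -0.0231, -0.0243, -0.0224, -0.0196, -0.0224 and -0.0212 in the first 6 of those settings, and from -0.0105 (without control replicate 2) to 0.12 without single libraries. The count of passing H3K4me1 lists (1) was 0 with an estimated correlation, by fry, at 2 kb or with TMM factors, 2 at 50 kb with fibroblast markers added, and 0 to 2 without single libraries.

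For H3K27me3 regions (0 by limma), the Wald test and voom gave 1 each and single libraries left out 0 to 1432, with 0 to 4 in the Pitx2 window. For H3K27me3 genes (1), size factors, loess offsets, voom, TMM factors, edgeR with TMM factors and the 50 kb distance gave 0 each, the Wald test and a robust prior 3 each, edgeR without TMM factors 4, the 2 kb distance 2 and single libraries left out 0 to 410. The Pitx2 gene (0.10) ranged from -0.0216 (without control replicate 2) to 0.22. The count of passing H3K27me3 lists (7) was 0 with an estimated correlation, 0 by fry, 1 at 2 kb and 0 to 9 without single libraries, where the 9 held 3 lists from outside the 7.

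For CTCF regions (0 by limma), size factors gave 21, loess offsets 20, the Wald test 5, voom 32, TMM factors 22, edgeR with TMM factors 21, a pseudocount of 0.5 gave 2, and single libraries left out 0 to 19453, with 0 to 26 in the Pitx2 window. For CTCF genes (0 by limma), size factors, loess offsets and TMM factors gave 4 each, the Wald test 2, voom and edgeR with TMM factors 5 each, the 50 kb distance 1 and single libraries left out 0 to 5958. The Pitx2 gene (-0.05) ranged from -0.62 to 0.51 and was above 0 without control replicate 1 (0.51) or deletion replicate 1 (0.18). In the upper 50 percent of abundance, correlations of fold changes were 0.137 for H3K27ac with H3K4me1, -0.265 with H3K27me3 and 0.172 with CTCF, -0.0247 for H3K4me1 with H3K27me3 and 0.0872 with CTCF, and 0.0325 for H3K27me3 with CTCF.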

Other observations

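These values were picked only after the result was seen, and no explanation was tested for them. At the end of chromosome X, by Mid1, which spans the boundary of the pseudoautosomal region in mice, the gene model G530011O06Rik was lower in both deletion libraries than in both controls for all 4 antibodies. It carried 192 and 80.1 tags of H3K4me1 and 49.5 and 13.6 of H3K27me3 (control and deletion means), and both passed by limma. In H3K27ac it had 179 ± 27.6 and 97.2 ± 10.2 tags (SD, n = 2; log2 -0.87, adjusted p = 0.786), and in CTCF 91.0 ± 52.0 and 51.8 ± 0.651 (adjusted p = 0.719). In H3K4me1 the summed regions of Mid1 itself carried 185.3, 183.97, 224.71 and 190.44 tags in control replicates 1 and 2 and deletion replicates 1 and 2.

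In the first intron of agouti, the coat colour gene, the H3K4me1 region at chromosome 2, 155018454 to 155021567 fell from 42.4 ± 1.55 to 18.9 ± 9.45 tags (SD, n = 2; log2 -1.21, adjusted p = 6.7e-04), with 12.2 in deletion replicate 1 and 25.57 in deletion replicate 2. Raet1a had 28.5 ± 1.29 and 20.97 ± 0.983 tags of H3K4me1, and Raet1c had 74.1 ± 2.03 and 56.3 ± 4.88 tags of H3K27me3, neither passing by limma. An H3K4me1 region at chromosome 2, 98666219 to 98667530, among the highest of the table, had 9120 ± 1401 and 7437 ± 1313 tags (log2 -0.30, adjusted p = 3.3e-04), although control replicate 1 (8129) lay below deletion replicate 2 (8366). Mitochondrial regions held 0.144, 0.110, 0.0494 and 0.110% of H3K4me1 tags and 0.171, 0.139, 0.0566 and 0.130% of H3K27me3 tags in control replicates 1 and 2 and deletion replicates 1 and 2.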
